A study of Mus musculus with 2112 samples.

How the data were processed

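Per the labels' protocols, single cells and pools of 100 cells were sorted into lysis buffer and profiled by SMART-seq2, a full-length protocol for polyadenylated RNA that carries no molecular identifiers. The authors deposited expected counts, the numbers of reads per gene estimated by RSEM, as whole numbers with no further scaling. The authors also deposited TPM, transcript abundances scaled within each well, in which the ribosomal RNA precursor Rn45s is among the genes and so enters the scaling. Per the submitters' processing notes, RSEM was run against the mm9 genome; its version, the aligner, the annotation and any trimming were not given. Both deposited tables hold 23366 gene symbols and 1 column per well, and each column was matched to its sample by its exact title. The TPM of 24 wells of 100 cells were not analysed here. No positions in the genome are given, since the tables carry gene symbols alone.

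Titles and labels disagree for 1 set of wells. The titles of wells whose plate label is 4 call the mice 1, 2 or 3 and the plate 1, while their mouse label reads 2-1, 2-2 or 2-3. The mouse and plate labels were used. Plates 1 and 2 are called plate set A, and plate 4 is called plate set B.

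Single cells that carry the submitters' quality labels few_genes, pct_trans (not explained in the labels) or plasma were left out, and cells labelled cycling were kept. Expected counts of the remaining cells were summed per animal, treatment and sorted population, and rounded; a sum needed at least 5 cells, which all 48 sums had, but 3 of the 4 old unstimulated MPP sums lacked when cells labelled cycling were left out. The animal is the replicate, identified by its age and mouse label. Choices of test, samples, covariates, gene lists, named genes and alternatives were made before the data were examined, except where a choice is said to have been made later.

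Gene counts were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr at its defaults), limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. For each population, the 4 groups of age and treatment were fitted together (16 sums) with the plate set as a covariate. The stimulation response is the mean over both ages of stimulated minus unstimulated, the age difference is old minus young, and the age difference in the response is the interaction of both. Unstimulated populations were compared in 1 fit of 21 sums with plate set and age as covariates. Responses of different populations were compared in 1 fit of all 48 sums in 12 groups. Expression is given as CPM, counts scaled to a common library total, after TMM scaling, as mean ± SD over animals, and log2 fold changes carry their standard error. Plots, values of single animals set apart from their group and values of plasma-labelled and kept wells are CPM without TMM scaling. The TPM were used in a limma fit of log2(mean TPM + 1), or + 0.1, over genes with a mean TPM of at least 5.

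Stimulated and unstimulated cells of 7 animals came from the same mouse. After group means were removed, sums of the same animal correlated across genes with a mean log2 CPM of at least 5 at a mean Pearson's r of 0.17 in LT-HSC, 0.17 in ST-HSC and 0.195 in MPP over 7 pairs; genes are not independent replicates. With the plate set removed as well, these means were -0.057, -0.046 and -0.06, so the plate set took up the shared part. A fit with the animal as a block in place of the plate set was run as an alternative, and its values stand beside each result that it changed.

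When a group had no count of a gene, the fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The genes named per comparison were, by rule, the 8 with the largest positive and the 8 with the largest negative log2 fold change among genes past the threshold with a mean log2 CPM of at least 4, up to 4 members with the smallest p of each list described, and a fixed set of receptors, regulators and cytokines. Symbols of predicted or unnamed genes were skipped, which left out 1 gene in each of 5 comparisons. At most 30 genes were taken per comparison, list members being dropped first; the order of dropping was chosen after the values were seen.

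The 21 gene lists were NF-κB and Toll-like receptor response genes, cytokines and chemokines, interferon response, immediate early genes, STAT3 and SOCS genes, the Toll-like receptor pathway, HSC identity, HSC ageing, megakaryocyte, myeloid, lymphoid, erythroid, cell cycle, plasma and B cell, T and NK cell, macrophage, stroma and endothelium, heat shock and stress, ribosomal protein and oxidative phosphorylation genes, and 4 regulators tied to the study (Itgb3, Klf5, Ikzf1 and Stat3). Spi1 was read as Sfpi1, and Ahsp, Ighm and Trbc2 were not in the tables. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Calls of members are given over all genes tested and, where the words say so, adjusted over the list alone.

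For measures per cell, reads were thinned at random to 236870 per cell, the 10th percentile of totals, which left 1267 cells and left out 141 shallower ones. The response score of a cell is the number of the 35 NF-κB and Toll-like receptor response genes with at least 1 read. A cell counts as above the threshold when its score exceeds the 95th percentile of unstimulated cells of its population and plate set. Shares per animal were compared by two-sided exact permutation tests (scipy 1.17.1 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3; figures with matplotlib 3.10.9). To set the score against other genes, 1000 random sets were drawn in which each response gene was replaced by 1 of the 50 other genes nearest in the share of stimulated cells that detect them. The smallest p these tests can give is 0.0079 for 4 old against 5 young animals and 0.0286 for 4 against 3. The share above the threshold and the share labelled cycling were planned; the mean score, the spread of the score, the number of all genes detected, the detection of single genes and the comparisons within animals were added after the data were seen.

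Counts were simulated with known changes on the same designs and put through the same fits. A log2 change of 2 was found in 40.9%, 32.8% and 47.8% of genes for the responses of LT-HSC, ST-HSC and MPP, 17.9% for the age difference in unstimulated LT-HSC, 29.9% for the age difference in stimulated LT-HSC, 34.3% for the difference in response between MPP and LT-HSC, and 1.5% to 6.1% for the interaction of age and treatment. False calls made up 1.4%, 9.5% and 2.3% of the calls for these responses and 10.4% of those for the difference in response between MPP and LT-HSC. Numbers of genes past a threshold are given either as such or as percentages of the genes tested in that comparison, a scale chosen after the results were seen; alternatives keep the denominator of the comparison as reported.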

Results

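Blood-forming cells were sorted from mouse bone marrow as long-term haematopoietic stem cells (LT-HSC), short-term haematopoietic stem cells (ST-HSC) and multipotent progenitors (MPP). They were kept in HSPC medium without stimulation or with LPS (100 ng/ml), the ligand of Tlr4, and Pam3CSK4 (1 µg/ml), a lipopeptide ligand of Tlr2, for 2 h. Gene expression was measured in 2112 wells, of which 2046 held single cells and 66 held pools of 100 cells. The cells came from 9 mice, 4 old and 5 young; unstimulated cells came from all 4 old mice and from 3 of the young ones. After quality labels were applied, 1408 single cells were kept, 58.1% of the cells of plate set A and 87.6% of those of plate set B. A kept cell held a median of 388798 counts, with 6721 in the lowest, and 3902 detected genes, and the medians of the 12 groups of population, age and treatment ran from 328052 to 424431.5 counts. The 48 sums per animal, treatment and population held 14 to 42 cells and 5773775 to 26698006 counts (median 10502669). Rn45s, the ribosomal RNA precursor, took 16.38% of the counts of kept cells and between 8.52% and 30.83% of a sum.

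The first question was how LT-HSC respond to the ligands. The main NF-κB feedback inhibitor Nfkbia rose from 122.6 ± 47.8 CPM in unstimulated cells (SD, n = 7) to 1676 ± 418.5 CPM in stimulated cells (n = 9), a log2 fold change of 3.90 ± 0.19 (adjusted p = 8.38e-10). The adhesion molecule Icam1 rose from 61.2 ± 28.9 to 1405 ± 319.5 CPM (log2 fold change 4.68 ± 0.26), and the antiviral effector Ifit1 from 56.03 ± 25.5 to 1467 ± 512.8 CPM (4.80 ± 0.30). Cd83, a surface marker of activated immune cells, went from 0.0482 CPM to 1371 ± 739.2 CPM, a ratio of 39100 (95% counting interval 13400 to 189000; adjusted p = 3.67e-10). Ptgs2, the inducible cyclooxygenase, rose to 808 ± 661.6 CPM (log2 fold change 14.37 ± 0.65) and the chemokine gene Ccl5 to 450 ± 322.9 CPM (13.07 ± 0.55). Itgb3, the integrin beta 3 chain, rose from 104.5 ± 82.1 to 793 ± 358.6 CPM (3.49 ± 0.20, adjusted p = 6.24e-09).

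In LT-HSC, 1403 genes rose and 985 fell among 12970 tested (edgeR), and 1088 and 840 of them changed at least 2-fold. Among NF-κB and Toll-like receptor response genes, 31 of 34 rose and 1 fell (camera adjusted p = 1.52e-54; 32 and 1 adjusted over the list alone). Interferon response genes rose in 25 of 29 cases (adjusted p = 9.47e-24), immediate early genes such as Junb (4.59 ± 0.27) in 21 of 26 (5.76e-23), and cytokines and chemokines in 15 of 22 (6.46e-13). The chemokine gene Cxcl10 reached 968 ± 440 CPM (log2 fold change 13.19 ± 1.15), and Il6, a cytokine of the acute phase, went from 0 counts to 18.1 ± 11.3 CPM (adjusted p = 0.000106). STAT3 and SOCS genes rose in 7 of 15 cases (3.09e-07), among them Cish, a suppressor of cytokine signalling (2.32 ± 0.17). Of the 4 study regulators 2 rose, Itgb3 and the transcription factor Stat3 (2.04 ± 0.18, adjusted p = 9.98e-07); this list was tied to the study, so its count (adjusted p = 1.27e-06) is not independent evidence. Klf5 (4.18 ± 1.63, adjusted p = 0.0864), Ikzf1 (-0.19 ± 0.25, 0.655), Tnf (5.92 ± 2.01, 0.0509), Tlr2 (2.24 ± 0.84, 0.0733) and Tlr4 (-1.05 ± 1.05, 0.533) did not pass the test.

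Among genes that fell in LT-HSC, Mycn, a MYC family transcription factor, went from 374.3 ± 121.3 to 13.6 ± 17.8 CPM (log2 fold change -5.45 ± 0.82, adjusted p = 0.000189). Cbfa2t3, a transcriptional corepressor, went from 127.5 ± 23.95 to 5.97 ± 6.76 CPM (-4.92 ± 0.81, adjusted p = 0.00042). HSC identity genes passed as lower (3 rose and 11 fell of 26, adjusted p = 0.0153), a call that did not hold at adjusted p = 0.27 with an estimated correlation. Cell cycle genes passed as lower with 3 of 36 members past the test (adjusted p = 0.00234; adjusted p = 0.605 with an estimated correlation). Heat shock and stress genes rose in 11 of 17 cases (7.23e-05; adjusted p = 0.0741 with an estimated correlation).

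**Figure D1:**
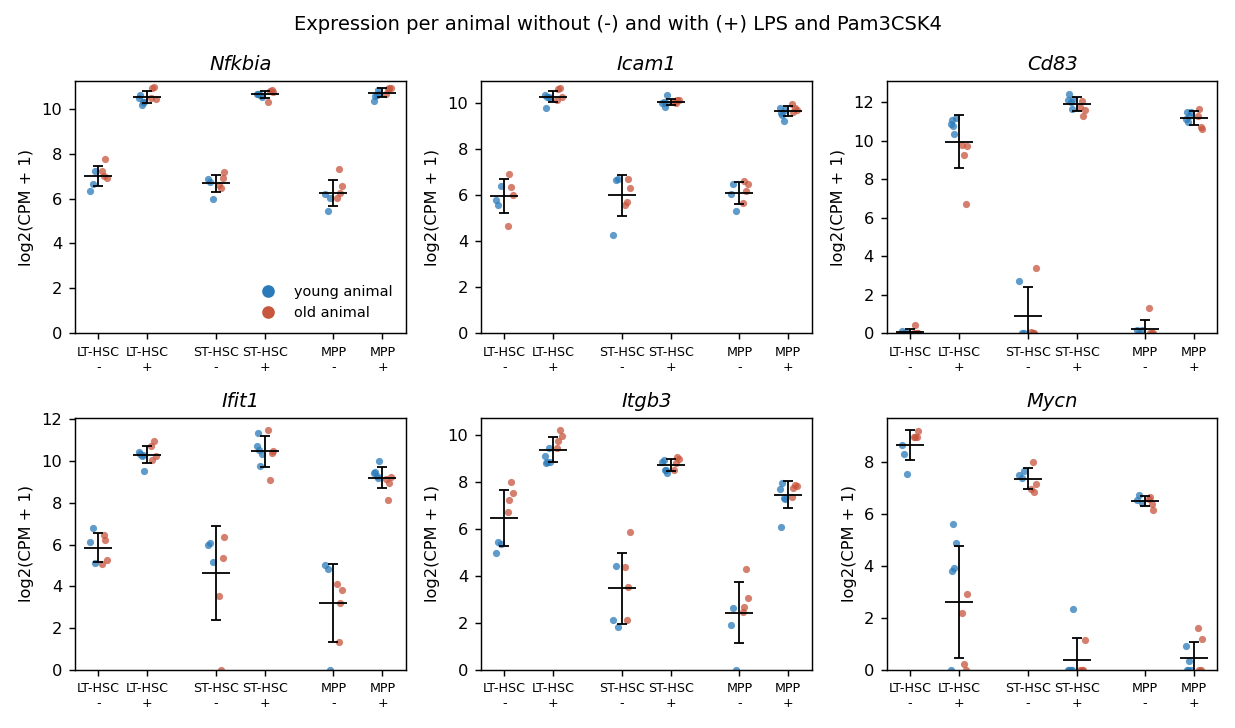
Expression of Nfkbia, Icam1, Cd83, Ifit1, Itgb3 and Mycn as log2(CPM + 1), without TMM scaling, per animal in unstimulated and stimulated LT-HSC, ST-HSC and MPP; lines with error bars show the mean ± SD over animals of both ages, blue points are young and red points old animals. Nfkbia, Icam1, Cd83, Ifit1 and Itgb3 were higher and Mycn was lower after stimulation.

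In ST-HSC the same question gave 1412 genes that rose and 908 that fell of 12733 tested. Nfkbia rose from 93.2 ± 22.6 (n = 7) to 1794 ± 246.1 CPM (n = 9; log2 fold change 4.29 ± 0.17, adjusted p = 1.13e-10). Relb, a subunit of the noncanonical NF-κB dimer, rose by 4.88 ± 0.19 (adjusted p = 1.01e-10). Itgb3 rose from 14.6 ± 16.8 to 475.04 ± 94.5 CPM (5.26 ± 0.59, adjusted p = 9.77e-06). The transcription factor Irf4 was at least 10100-fold higher, the plasminogen activator Plat at least 5640-fold and the stress-induced transcription factor Atf3 at least 4370-fold. Nr4a1, an immediate early nuclear receptor, rose by 12.52 ± 0.81, and Tnf from 1.13 to 63.5 CPM (5.85 ± 1.33, adjusted p = 0.00568).

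Mycn fell in ST-HSC from 148.3 ± 43.2 to 0.602 CPM (log2 fold change -8.61 ± 1.12, adjusted p = 4.81e-05). Among NF-κB and Toll-like receptor response genes, 33 of 35 rose and 1 fell (adjusted p = 8.36e-61). Interferon response genes rose in 25 of 29 cases (7.26e-22) and cytokines and chemokines in 15 of 21 (7.09e-09). Immediate early genes rose in 19 of 25 cases (1.32e-16) and STAT3 and SOCS genes in 9 of 15, with 1 lower (1.5e-05). Of the study regulators 3 of 4 rose (adjusted p = 0.000793), which is not independent evidence: Itgb3, Stat3 (1.46 ± 0.21, adjusted p = 0.000124) and Klf5, at a ratio with a 95% counting interval of 32.3 to 7240 (adjusted p = 0.0266). Klf5 was seen in 6 of 9 stimulated animals and had an adjusted p of 0.133 with the animal as a block. It missed the threshold without old mouse 2-3 (0.0562), old mouse 3 (0.0652), young mouse 1 (0.0589), young mouse 2-1 (0.0701) or young mouse 2-3 (0.0861). Cell cycle genes passed as lower (10 of 36, adjusted p = 3.93e-05; adjusted p = 0.294 with an estimated correlation), as heat shock genes did as higher (9 of 17, 7.22e-06; adjusted p = 0.0615 with an estimated correlation). HSC identity genes did not pass (6 rose and 8 fell of 25, adjusted p = 0.0775), but passed as lower without cells labelled cycling (0.0136; 0.0136 to 0.127 over its alternatives). Plasma and B cell genes passed as higher with Irf4 in the lead (2 rose and 1 fell of 8, adjusted p = 0.00698), a call that was lost at adjusted p = 0.0835 with an estimated correlation and at 0.112 with the animal as a block.

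In MPP, 1486 genes rose and 1173 fell of 12664 tested. Nfkbia rose from 74.3 ± 32.3 (n = 7) to 1854 ± 307.4 CPM (n = 9; log2 fold change 4.77 ± 0.20, adjusted p = 8.21e-11), and Cd83 reached 2524 ± 525.4 CPM (13.66 ± 0.65). Tnf, a main inflammatory cytokine, rose from 0.804 to 158.1 ± 42.8 CPM (8.22 ± 0.78, adjusted p = 1.2e-06), and the chemokine gene Ccl4 from 11.2 to 617.95 ± 320.04 CPM (5.85 ± 0.37). The cytokine gene Il1b was at least 3210-fold higher and the chemokine gene Cxcl2 at least 2290-fold, and Bcl2a1d, a survival gene of the BCL2 family, rose by 11.91 ± 0.49. Itgb3 rose from 5.84 ± 6.08 to 201.6 ± 66.5 CPM (5.57 ± 0.55, adjusted p = 1.69e-06), and Ikzf1, a lymphoid transcription factor, from 116.5 ± 22.3 to 283.3 ± 105.1 CPM (1.30 ± 0.21, adjusted p = 0.000285).

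Mycn fell in MPP from 81.2 ± 10.2 to 0.506 CPM (log2 fold change -7.79 ± 0.83, adjusted p = 3.88e-06). Tet1, a DNA demethylase, fell from 66.6 ± 21.8 to 3.99 CPM (-4.10 ± 0.71). Of NF-κB and Toll-like receptor response genes 32 of 35 rose (adjusted p = 8.4e-73), of interferon response genes 25 of 29 (2.49e-22) and of cytokines and chemokines 15 of 22 (7.35e-16). Of STAT3 and SOCS genes 9 of 14 rose (2.17e-08) and of heat shock genes 11 of 17, with 1 lower (2.15e-10). Immediate early genes rose in 14 of 23 cases, with 1 lower (4.35e-14). Cell cycle genes fell in 19 of 36 cases (2.98e-09; 28 adjusted over the list alone), and lymphoid genes in 7 of 15 (adjusted p = 0.00296). Both calls held with an estimated correlation, as those of all 9 lists did in MPP, but that of cell cycle genes ended without cells labelled cycling (adjusted p = 0.432, the highest over its alternatives). Of the study regulators 3 of 4 rose (1.12e-05), which is not independent evidence. Without cells labelled cycling, 450 genes passed in MPP, and the calls of Ikzf1 (adjusted p = 0.0536) and Il6 (0.224; 8.35 ± 1.83 and 0.00495 with them) ended. That setting kept 1 of 4 old unstimulated MPP sums (mouse 2-2, 6 cells), so the loss of cycling cells and of 3 animals cannot be told apart in it.

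Of 11899 genes tested in all 3 populations, 6.42% rose in all 3, against 0.149% if the calls were independent, and 2.09% fell in all 3, against 0.0479%. In young animals 5.62%, 6.74% and 9.25% of tested genes passed in LT-HSC, ST-HSC and MPP, and in old ones 10.29%, 7.99% and 8.11%, whose difference the interaction tests. With the animal as a block, 1734, 1693 and 1971 genes passed, of which 1560, 1485 and 1757 were the same genes. The division into higher and lower genes depended on the scaling. Log2(mean TPM + 1) gave 1092 and 2395 genes in LT-HSC, 1036 and 2195 in ST-HSC and 1007 and 2264 in MPP. DESeq2 gave 1538 and 1597 in ST-HSC. The median log2 fold change of all genes was -0.125, -0.114 and -0.106 with TMM, -0.180, -0.226 and -0.121 with median-of-ratios factors, and -0.349, -0.355 and -0.301 with log2(mean TPM + 1).

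Other lists did not pass under stimulation in any population. Genes of the Toll-like receptor pathway rose in 6 of 19, 4 of 19 and 7 of 20 cases in LT-HSC, ST-HSC and MPP, with 1 lower in MPP (adjusted p = 0.0993, 0.0725 and 0.0655). With the animal as a block the list passed in ST-HSC (0.0345) and MPP (0.0322). Adjusted p values in the same order were 0.807, 0.838 and 0.402 for HSC ageing, 0.868, 0.838 and 0.637 for megakaryocyte, 0.868, 0.756 and 0.67 for myeloid, 0.44, 0.922 and 0.659 for erythroid, 0.868, 0.838 and 0.659 for T and NK cell genes. They were 0.426, 0.838 and 0.728 for macrophage, 0.868, 0.475 and 0.637 for stroma and endothelium, 0.17, 0.191 and 0.124 for ribosomal protein, and 0.36, 0.475 and 0.406 for oxidative phosphorylation genes.

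The next question was whether MPP and LT-HSC respond differently, which was tested as the difference of their log2 fold changes. Tgm2, transglutaminase 2, was at 1310 ± 471.9 CPM in stimulated MPP and 506.4 ± 170 CPM in stimulated LT-HSC (SD, n = 9 each; difference of log2 fold changes 8.72 ± 0.65, adjusted p = 2.25e-12). Without stimulation it was at 3.27 CPM in MPP and 679.3 ± 349.5 CPM in LT-HSC (n = 7 each), so its mean was higher after stimulation in MPP and lower in LT-HSC. Ccl4 reached 611.1 ± 312.3 against 42.8 ± 36.8 CPM (difference 3.15 ± 0.57, adjusted p = 0.00174), and Ltb, a lymphotoxin subunit, 448.8 ± 213.4 against 171.1 ± 105.2 CPM (2.78 ± 0.36, 4.97e-06). For Plk2, a polo-like kinase gene with a lower unstimulated level in MPP, the difference was 9.73 ± 1.53 (0.000253). The difference was negative for Coq10b, a coenzyme Q binding protein gene (-5.02 ± 0.87, 0.000884), and Tubb6, a tubulin gene (-3.39 ± 0.65, 0.00303).

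In all, the log2 fold change was higher in MPP than LT-HSC for 63 genes and lower for 50 among 14451 tested, against 1.54% and 1.70% of them with DESeq2. The sign of the difference does not tell a rise in 1 population from a fall in the other. Ikzf1 passed as well (1.49 ± 0.30, adjusted p = 0.00462), while Itgb3 (2.06 ± 0.59, 0.0885), Nfkbia (0.87 ± 0.23, 0.0519), Tnf (2.91 ± 1.73, 0.759) and Stat3 (-0.32, 0.949) did not. HSC identity was the list that passed (1 of 26 higher, adjusted p = 0.0269), and its call ended at adjusted p = 0.148 with an estimated correlation and at 0.13 with the animal as a block. Between ST-HSC and LT-HSC 4 genes differed in response. The difference was positive for Tgm2 (3.59 ± 0.57, adjusted p = 0.000978). It was negative for Coq10b (-5.25 ± 0.87, 0.00208), the RNA-decay gene Zfp36 (-2.43 ± 0.47, 0.0232) and the actin gene Actg1 (-0.82 ± 0.12, 0.000202). Cell cycle genes passed there as lower (0 of 36; 0.00188; adjusted p = 0.974 with an estimated correlation). With the animal as a block 55 genes differed between MPP and LT-HSC, 46 of them the same, and Ikzf1 did not (0.232). The count was 61 without old mouse 2, 72 without old mouse 2-2, 71 without old mouse 2-3, 49 without young mouse 2-1 and 65 without young mouse 2-3. Ikzf1 missed the threshold without old mouse 2-3 (0.054) or young mouse 2-1 (0.0602), and without cells labelled cycling Ikzf1 (0.119) and Tubb6 (0.659) did and Coq10b turned to 0.08, with 1 of 4 old unstimulated MPP sums left.

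Read at equal depth in single cells, Tnf was detected in 50.9% ± 12.3 of stimulated MPP and 8.55% ± 7.56 of stimulated LT-HSC (SD, n = 9; exact permutation test within animals, adjusted p = 0.0169 over 26 tests chosen after the data were seen). Itgb3 was detected in 71.3% ± 13.98 of stimulated MPP and 91.3% ± 4.53 of LT-HSC, lower in MPP in 9 of 9 animals (exact adjusted p = 0.0169). In unstimulated cells Itgb3 was detected in 8.2% of MPP, and in 26.1% to 79.3% of the LT-HSC of an animal.

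**Figure D2:**
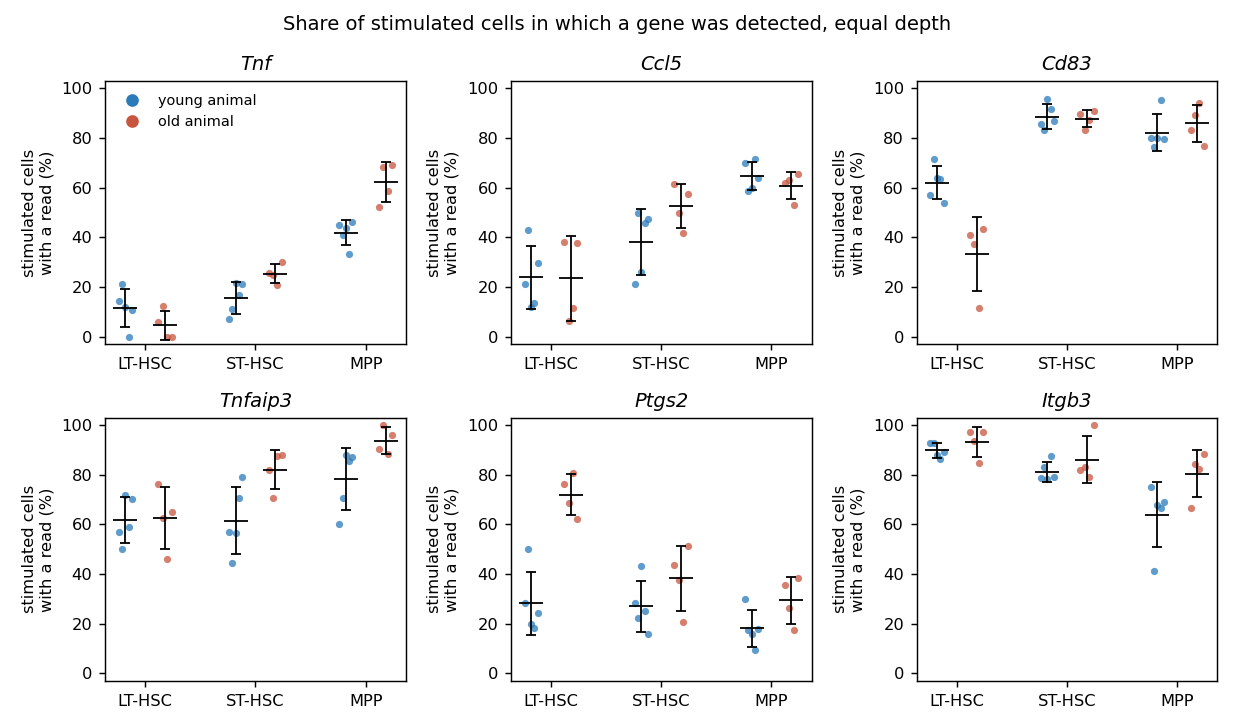
Share of stimulated cells (%) with at least 1 read of Tnf, Ccl5, Cd83, Tnfaip3, Ptgs2 and Itgb3 after thinning to equal depth, per animal, in LT-HSC, ST-HSC and MPP; lines with error bars show the mean ± SD over animals of each age, young in blue and old in red. Tnf, Ccl5, Cd83 and Tnfaip3 were detected in more MPP than LT-HSC, and Ptgs2 and Itgb3 in fewer.

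The series asks whether the response of single cells changes with age, and the planned measure was the share of stimulated cells whose NF-κB response score exceeds the threshold set on unstimulated cells. In LT-HSC 98.6% ± 1.63 of old (SD, n = 4) and 94.9% ± 1.98 of young cells (n = 5) were above it (two-sided exact permutation p = 0.0317, adjusted p = 0.0952 over 3 populations). In ST-HSC the shares were 98.96% ± 2.08 and 94.5% ± 5.99 (exact adjusted p = 0.3095), and in MPP 98.2% ± 3.57 and 95.8% ± 4.26 (exact adjusted p = 0.4444), so no population passed by the planned measure. With Rn45s left out before thinning, an alternative chosen after the data were seen, LT-HSC passed (6.98 points, exact adjusted p = 0.0476; 0.0476 to 0.4048 over its alternatives). Of unstimulated cells 3.62% of LT-HSC, 3.32% of ST-HSC and 5.21% of MPP were above the same threshold. Old minus young was 2.8 and 4.3 percentage points within plate sets A and B in LT-HSC, 9.2 and -2.1 in ST-HSC, and 3.4 and 0.0 in MPP.

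The mean number of the 35 response genes detected per stimulated cell, a measure added after the data were seen, was higher in old than young MPP, at 25.02 ± 1.48 against 22.2 ± 0.713 genes (SD, n = 4 and 5; exact permutation p = 0.0079, the smallest possible, adjusted p = 0.0238). In ST-HSC it was 23.2 ± 1.52 against 20.9 ± 1.02 (exact adjusted p = 0.0476), and in LT-HSC 21.5 ± 1.22 against 20.8 ± 0.649 (exact adjusted p = 0.3254). Within plate sets A and B the old and young means were 25.7 and 22.3, and 24.4 and 22.1, in MPP, and 24.3 and 20.7, and 22.1 and 21.2, in ST-HSC. Unstimulated MPP had 9.18 genes in old and 7.93 in young animals. Of all genes, a stimulated cell read at equal depth detected 4376.6 ± 527.1 in old and 3602.7 ± 297.4 in young MPP (exact permutation p = 0.0397, adjusted p = 0.119). In ST-HSC the means were 3510.8 and 3016.4 (exact adjusted p = 0.2262), and in LT-HSC 3515.9 and 3492.7 (0.9365). Of 1000 random sets of other genes matched on detection, 33.6% differed between ages by as much as the response genes in MPP and 8.0% in ST-HSC, so the difference was not shown to exceed that of other genes.

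Age differences in unstimulated cells are the baseline of the aged response. In LT-HSC, Nupr1, a stress-induced chromatin protein, was at 123.9 ± 28.3 CPM in old (SD, n = 4) and 11.7 ± 2.88 CPM in young animals (n = 3; log2 fold change 3.30 ± 0.37, adjusted p = 0.00185). Itgb3 was higher in old LT-HSC, at 157.6 ± 68.4 against 33.7 ± 6.43 CPM (2.29 ± 0.28, adjusted p = 0.00237). So were the immediate early gene Jun, at 68.99 ± 25.3 against 5.09 ± 3.45 CPM (3.96 ± 0.51, 0.00312), and the membrane trafficking gene Ehd3, at 170.4 ± 48.9 against 40.1 ± 16.1 CPM (2.18 ± 0.33, 0.0169). Junb was higher by 2.10 ± 0.35 (0.0342). Lower in old were Kpna2, a nuclear import factor (-2.75 ± 0.45, 0.0282), Cks2, a subunit of cell cycle kinases (-2.45 ± 0.40, 0.0274), and Coq10b, lower at a ratio with a 95% counting interval of 37.2 to 1130 (0.00446). Vwf, the von Willebrand factor gene, was at 387.7 ± 108.8 against 102.01 ± 50.3 CPM, which did not pass (1.86 ± 0.42, 0.177), and Selp (3.11 ± 1.31, 0.613) and Slamf1 (1.19 ± 0.85, 0.953) did not pass either.

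These 5 higher and 3 lower genes were all that passed in unstimulated LT-HSC among 12970, 939 having an unadjusted p under 0.05; DESeq2 called 0.995% higher and 0.663% lower, and log2(mean TPM + 1) 24 and 22 genes. HSC ageing genes were higher in old LT-HSC (3 of 30, or 6 adjusted over the list alone; adjusted p = 2.99e-31), and the lists of HSC identity (0 of 26, or 3 over the list alone; 1.91e-09) and STAT3 and SOCS genes (0 of 15; 3.6e-05) passed as higher. Cell cycle genes passed as lower (0 of 36, or 8 adjusted over the list alone; 9.85e-33). These calls held with an estimated correlation, but that of cell cycle genes ended without cells labelled cycling (adjusted p = 0.15, the highest over its alternatives). With an estimated correlation so did that of the study regulators as higher (1 of 4; 0.000215), which is not independent evidence. Calls lost with an estimated correlation were those of immediate early genes as higher (2 of 26; 2.94e-05; adjusted p = 0.0595 with an estimated correlation), ribosomal protein genes as higher (7.46e-07; adjusted p = 0.448) and megakaryocyte genes as higher (1 of 20; 0.0275; adjusted p = 0.193), whose mean log2 fold change was -0.359 at a median of 0.316. Calls as lower lost in the same way were those of oxidative phosphorylation (2.94e-05; adjusted p = 0.364), erythroid (0.0247; adjusted p = 0.0669) and stroma genes (0.0275; adjusted p = 0.183). Of these 3 lists and the ribosomal protein genes 0 members passed the test. Nupr1 passed in every setting run, while without cells labelled cycling Jun (adjusted p = 0.603), Ehd3 (0.592), Junb (0.592), Cks2 (0.932) and Coq10b (0.387) missed the threshold and Kpna2 turned to 0.46. Itgb3 missed it with all cells (0.391) or with pools (0.929). Jun (0.929), Ehd3 (0.338), Junb (0.938), Kpna2 (0.929) and Cks2 (0.939) also missed it with pools. Ehd3 (0.083), Junb (0.0506), Kpna2 (0.083) and Cks2 (0.13) missed it without the plate set term, and Coq10b (0.067) with log2(mean TPM + 1). The count was 5 without old mouse 2, 3 without old mouse 2-3 and 5 without old mouse 3. Ehd3 missed the threshold without old mouse 2-3 (0.067), old mouse 3 (0.0981), young mouse 1 (0.115) or young mouse 2-1 (0.0857). Coq10b missed it without old mouse 2-3 (0.067). Junb missed it without old mouse 2 (0.099), 2-3 (0.151) or 3 (0.113) or young mouse 1 (0.113), 2 (0.0549) or 2-3 (0.0675). Kpna2 missed it without old mouse 2 (0.114), 2-3 (0.117) or 3 (0.113) or young mouse 1 (0.147), 2 (0.0501) or 2-1 (0.0917). Cks2 missed it without old mouse 2 (0.114), 2-2 (0.106), 2-3 (0.0774) or 3 (0.136) or young mouse 1 (0.0806), 2-1 (0.107) or 2-3 (0.1).

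**Figure D3:**
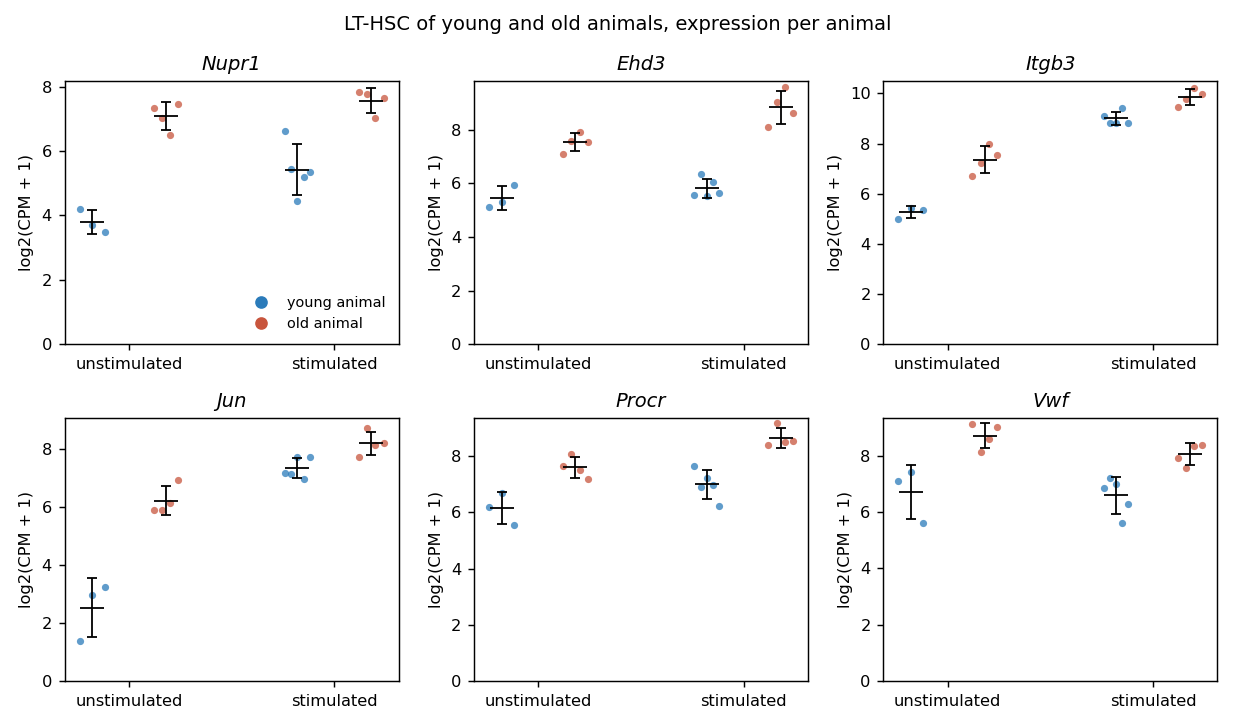
Expression of Nupr1, Ehd3, Itgb3, Jun, Procr and Vwf as log2(CPM + 1), without TMM scaling, in LT-HSC of young (blue) and old (red) animals, unstimulated and stimulated; points are animals and lines with error bars the mean ± SD over animals. Nupr1, Ehd3 and Itgb3 were higher in unstimulated old LT-HSC, and Nupr1, Ehd3 and Procr in stimulated old LT-HSC.

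In stimulated LT-HSC 29 genes were higher and 12 lower in old animals. Ehd3 was at 572.3 ± 284.1 CPM in old (SD, n = 4) and 59.8 ± 14.9 CPM in young animals (n = 5; log2 fold change 3.12 ± 0.29, adjusted p = 0.000105). Nupr1 was at 221.4 ± 42.4 against 49.2 ± 29.2 CPM (2.29 ± 0.30, 0.00205), and Anxa1, a phospholipid binding protein that dampens inflammation, was at 634.1 ± 181.2 against 75.6 ± 45.3 CPM (3.07 ± 0.45, 0.00383). The glycolytic enzyme gene Hk2 was higher, at 296.1 ± 112.7 against 18.7 ± 11.7 CPM (3.91 ± 0.58, 0.00404), as was Il4ra, a cytokine receptor chain (2.90 ± 0.41, 0.0034). Lower in old were the kinase gene Syk, at 15.02 ± 6.82 against 87.3 ± 19.7 CPM (-2.53 ± 0.37, 0.00383), and the lipid phosphatase gene Inpp5d, at 76.8 ± 15.3 against 216.7 ± 18.1 CPM (-1.58 ± 0.22, 0.00278). The tyrosine phosphatase gene Ptpn6 was lower as well (-1.55 ± 0.30, 0.0294). Itgb3 was at 1099 ± 312.01 against 548.7 ± 126.7 CPM (0.96 ± 0.22, 0.0911) and Vwf differed by 1.59 ± 0.35 (0.0727), neither passing.

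HSC ageing genes were higher in stimulated old LT-HSC too (6 of 30, or 20 adjusted over the list alone; adjusted p = 1.56e-34), and STAT3 and SOCS genes passed as a list (1 of 15 higher; 1.06e-05), both also with an estimated correlation. Procr, an HSC marker, was higher (1.71 ± 0.27, 0.00828), and HSC identity genes passed (2 of 26; 0.0264; adjusted p = 0.345 with an estimated correlation). Other calls that were lost with an estimated correlation were those of immediate early (0.000808; adjusted p = 0.158), heat shock (0.00917; adjusted p = 0.345), ribosomal protein (0.0289; adjusted p = 0.854) and plasma and B cell genes (0.0299; adjusted p = 0.158) as higher. Those of oxidative phosphorylation (0.000422; adjusted p = 0.477) and cell cycle genes (0.00232; adjusted p = 0.52) as lower were lost too, and 0 members of these 6 lists passed the test. DESeq2 gave 1.80% higher and 1.42% lower genes of those tested, log2(mean TPM + 1) 52 and 49 genes, and + 0.1 35 and 40; 19 genes passed without cells labelled cycling, where Syk (0.0583) and Il4ra (0.0821) missed the threshold. The count was 24 without old mouse 2, 21 without old mouse 2-2, 23 without old mouse 2-3, 24 without old mouse 3 and 21 without young mouse 2-3. Procr missed the threshold without old mouse 2 (0.0632), 2-2 (0.0749), 2-3 (0.0502) or 3 (0.0577) or young mouse 2-3 (0.0508). The log2 fold change of Inpp5d turned to 0.05 in pools.

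At equal depth, single LT-HSC of old animals detected Vwf more often, in 78.2% of unstimulated cells against 36.8% in young animals (n = 4 and 3; exact permutation adjusted p = 0.0381 over 12 tests chosen after the data were seen). In stimulated cells the shares were 61.5% against 22.8% (n = 4 and 5; exact adjusted p = 0.019). For Selp, an adhesion molecule of platelets, the shares were 77.5% against 20.3% (exact adjusted p = 0.0381) and 61.2% against 9.41% (0.019). Slamf1 was detected in 53.8% against 21.7% and in 25.4% against 8.16%, and Nupr1 in 84.01% against 37.7% and in 76.8% against 36.2%, with the same exact adjusted p values. Itgb3 was detected in 64.1% against 33.6% of unstimulated (exact adjusted p = 0.0935) and 93.2% against 89.9% of stimulated cells (0.3095). Jun was detected in 37.6% against 7.04% of unstimulated (exact adjusted p = 0.0686) and 73.7% against 53.4% of stimulated cells (0.019).

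Age differences were also tested in ST-HSC and MPP. In stimulated ST-HSC, Actg1 was higher in old animals, at 8060 ± 366.3 CPM (SD, n = 4) against 4861 ± 622.6 CPM (n = 5; log2 fold change 0.72 ± 0.09, adjusted p = 0.00494). The membrane protein gene Serinc3 was lower, at 98.2 ± 27.4 against 336.6 ± 113.6 CPM (-1.73 ± 0.24, 0.0132). Serinc3 was lower in stimulated old MPP as well, at 119.2 ± 19.3 against 332.5 ± 81.9 CPM (-1.47 ± 0.22, 0.017). H2-Aa, an MHC class II chain, was higher there, at 164.6 ± 31.3 against 27.3 ± 21.1 CPM (2.79 ± 0.39, 0.017). In unstimulated MPP the NF-κB subunit gene Nfkb2 was higher in old animals, at 27.8 ± 10.2 (n = 4) against 1.56 ± 1.38 CPM (n = 3; 4.01 ± 0.54, 0.014). The interferon-induced GTPase gene Gbp3 was higher too (1.63 ± 0.25, 0.0361).

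The other genes of these counts were Frmd4b (0.0384), Ydjc (0.0227) and Amacr (0.04), higher in stimulated old ST-HSC. In stimulated MPP Dynlt1b (-1.98 ± 0.29, 0.017) and Tmem181b-ps (-1.33 ± 0.22, 0.0346) were lower and 1700112E06Rik (0.017) was higher. Ydjc, Amacr and 1700112E06Rik were named after their values were seen. In unstimulated ST-HSC edgeR called 0 genes, with 4.45% of tested genes at an unadjusted p under 0.05, and DESeq2 called 62 higher and 28 lower. In stimulated ST-HSC edgeR called 4 genes higher and 1 lower, and DESeq2 1.01% and 0.526% of tested genes. In stimulated MPP edgeR called 2 and 3 genes and DESeq2 89 and 59. In unstimulated MPP edgeR called 2 and 0 genes and DESeq2 37 and 39. The fit of log2(mean TPM + 1) called 8 and 5 genes in stimulated ST-HSC and 7 and 3 in stimulated MPP. Leaving out any of the 4 old mice left 0 genes in stimulated MPP, where H2-Aa had an adjusted p of 0.0953 without old mouse 2, 0.0825 without 2-2, 0.074 without 2-3 and 0.221 without 3. Without cells labelled cycling the count was also 0. In stimulated ST-HSC the count was 0 without old mouse 2-2 or 3, 1 without old mouse 2-3 or young mouse 2-3, 3 without young mouse 2 or 2-1 and 2 without young mouse 3. Serinc3 missed the threshold there without any of the old mice (0.0876, 0.0805, 0.0771 and 0.0732 for 2, 2-2, 2-3 and 3). Actg1 missed it without old mouse 2-2 (0.0805) or 3 (0.0732). Nfkb2 missed it without old mouse 2 (0.0744), 2-2 (0.0999) or 3 (0.071) or young mouse 1 (0.0551) or 2-1 (0.0613), and in pools turned to -0.34. The count in unstimulated MPP was 0 without old mouse 2, 2-2 or 3 or young mouse 1, and 1 without young mouse 2, 2-1, 2-3 or 3.

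As lists ranked against other genes, HSC ageing passed as higher in unstimulated old ST-HSC (0 of 26 members past the test, 1 adjusted over the list alone; adjusted p = 1.4e-08) and cell cycle genes in stimulated old MPP (0 of 36, or 10 adjusted over the list alone; 4.64e-22). Both held with an estimated correlation. The latter call ended without cells labelled cycling (adjusted p = 0.488, the highest over its alternatives). Other list calls were lost with an estimated correlation, and none of these lists had a member past the test except the NF-κB genes (1 of 35). In unstimulated ST-HSC these were cell cycle (1.26e-10; adjusted p = 0.295), ribosomal protein (0.000889; adjusted p = 0.711), erythroid (0.002; adjusted p = 0.425) and megakaryocyte genes (0.0131; adjusted p = 0.217) as higher and interferon response genes (0.0173; adjusted p = 0.571) as lower. In unstimulated MPP these were cell cycle (6.05e-10; adjusted p = 0.119), NF-κB (0.0428; adjusted p = 0.121), oxidative phosphorylation (0.0428; adjusted p = 0.792) and HSC ageing genes (0.0468; adjusted p = 0.237) as higher. HSC identity (0.00665; adjusted p = 0.119), STAT3 and SOCS (0.0197; adjusted p = 0.119) and heat shock genes (0.0468; adjusted p = 0.303) were those as lower. In stimulated cells they were cell cycle genes as higher in ST-HSC (1.68e-10; adjusted p = 0.849) and interferon response genes as lower in MPP (0.015; adjusted p = 0.756).

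The interaction of age and treatment asks whether old and young cells respond differently. In LT-HSC 1 gene passed, Coq10b, whose log2 fold change was higher in old animals by 7.57 ± 1.07 (adjusted p = 0.0333). Its stimulated level was 100.9 ± 29.5 CPM in old (SD, n = 4) and 53.6 ± 21.2 CPM in young animals (n = 5), and its unstimulated level was lower in old animals. Itgb3 differed in response by -1.33 ± 0.35 in LT-HSC (adjusted p = 0.505), -0.92 ± 1.02 in ST-HSC and -1.50 ± 0.87 in MPP (adjusted p = 1 in both), and Nfkbia by -0.17 ± 0.32 in LT-HSC (1). Coq10b did not pass with the animal as a block (0.572), without cells labelled cycling (0.68), or without old mouse 2 (0.115), 2-2 (0.131), 2-3 (0.231) or 3 (0.153) or young mouse 2 (0.0662), 2-1 (0.097), 2-3 (0.181) or 3 (0.0921).

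The edgeR count was 0 in ST-HSC, with 4.72% of genes at an unadjusted p under 0.05, and 0 in MPP, with 4.69%, while 6.82% had such a p in LT-HSC. DESeq2 called 95 genes with a higher and 86 with a lower log2 fold change in old LT-HSC, 55 and 54 in ST-HSC, and 42 and 46 in MPP. As a list ranked against other genes, the log2 fold changes of HSC ageing genes passed as lower in old than young ST-HSC (0 of 26 members past the test, and 0 adjusted over the list alone; adjusted p = 0.00112, adjusted p = 0.0184 with an estimated correlation). Calls lost with an estimated correlation were those of cell cycle genes in LT-HSC (1.74e-10; adjusted p = 0.575), ribosomal protein genes in ST-HSC (0.00938; adjusted p = 0.949) and cell cycle and heat shock genes in MPP (0.0271 and adjusted p = 0.567 for each, and 0.208 with the animal as a block for heat shock), none with a member past the test. HSC identity genes passed in LT-HSC with the animal as a block (0.0399), and HSC ageing genes (0.0356) and the study regulators (0.0336) without cells labelled cycling. Without old mouse 2-2 the count in LT-HSC was 2 and without young mouse 1 it was 3; it was 1 in ST-HSC without old mouse 2-3, and 1 in MPP without old mouse 2-3, young mouse 2-1 or young mouse 2-3.

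The sorted populations differ in stage, and their unstimulated profiles were compared to give the baseline of the responses. In MPP against LT-HSC, Mpo, the myeloperoxidase of granule-forming cells, was at 1548 ± 1120 CPM against 0.00947 CPM (SD, n = 7 each), a ratio of 125000 (95% counting interval 22500 to 4960000). Dntt, the DNA polymerase of lymphoid precursors, was at least 18200-fold higher. Flt3, a receptor of multipotent and lymphoid progenitors, was at 600.2 ± 157.96 against 12.5 ± 12.7 CPM (log2 fold change 5.61 ± 0.71, adjusted p = 1.54e-05). Procr was lower by 3.42 ± 0.33 on the log2 scale (12.6 ± 4.35 against 146.8 ± 78.7 CPM, 5.7e-07), Mmrn1, a platelet granule protein, by 3.94 ± 0.35, and Nupr1 was lower by 8.10 ± 1.10. Of HSC identity genes 20 of 25 were lower (adjusted p = 5.5e-34), of HSC ageing genes 24 of 29 (1.41e-32) and of megakaryocyte genes 10 of 20 (3.13e-13). Lymphoid (7 of 10, 1.56e-15) and myeloid genes (6 of 19, 3.64e-11) were higher.

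In MPP against LT-HSC 4.74% of 12041 genes were higher and 5.61% lower. Lists that passed but not with an estimated correlation were cell cycle (11 of 36 higher, 1.56e-15; adjusted p = 0.141), oxidative phosphorylation (8 of 71 higher, 4.38e-06; adjusted p = 0.355), and cytokine genes (3 of 10 higher, 0.0407; adjusted p = 0.1). The same held for interferon response (8 of 29 lower, 6.93e-06; adjusted p = 0.1) and STAT3 and SOCS genes (3 of 13 lower, 0.00621; adjusted p = 0.138). Without cells labelled cycling 2.08% of them passed, with 1 of 4 old MPP sums left. The number, 1246 in all, was 818 without old mouse 2 and 817 without old mouse 3.

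In ST-HSC against LT-HSC 0.963% of genes were higher and 0.498% lower. Flt3 was at 247.95 ± 104.9 against 12.5 ± 12.7 CPM (4.30 ± 0.66, n = 7 each, adjusted p = 0.00112). Dntt went from 0 counts to 21.6 ± 22.2 CPM, and Cd53, a leukocyte tetraspanin, was higher by 4.63 ± 0.86 (0.00538). Clu, the chaperone clusterin, was lower by 9.79 ± 1.56 (0.00142), Sult1a1, a sulfotransferase, by 3.83 ± 0.59 (0.00112), and Vwf by 4.92 ± 1.04 (15.4 ± 13.2 against 301.1 ± 197.8 CPM, 0.0148). HSC ageing (10 of 29 lower, 8.55e-31), megakaryocyte (3 of 20 lower, 3.48e-09), lymphoid (4 of 10 higher, 1.21e-11) and cytokine genes (1 of 10 higher, 0.0014) passed with either correlation. HSC identity (3 of 25 lower, 6.09e-08; adjusted p = 0.0533 with an estimated correlation), myeloid (1 of 19 higher, 0.00651; adjusted p = 0.133), T and NK cell (1 of 2 higher, 0.042; adjusted p = 0.133) and ribosomal protein genes (lower, 0.00657; adjusted p = 0.934) did not. Vwf missed the threshold without old mouse 2 (0.069), 2-2 (0.0592), 2-3 (0.0592) or 3 (0.0633). Without these mice in turn 0.938%, 0.723%, 0.914% and 0.689% of tested genes passed, and 56 genes passed without cells labelled cycling.

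Cells labelled cycling by the submitters were compared between ages because cycling differs between the populations. In stimulated MPP 57.2% ± 2.60 of old (SD, n = 4) and 31.2% ± 4.73 of young cells (n = 5) were labelled cycling (two-sided exact permutation p = 0.0079, adjusted p = 0.0476 over 6 tests). In unstimulated LT-HSC the share was 9.29% ± 4.81 in old (n = 4) and 51.4% ± 10.9 in young animals (n = 3; exact p = 0.0286, the smallest possible, adjusted p = 0.0635). In unstimulated MPP the shares were 87.2% ± 6.93 and 67.5% ± 7.96 (exact adjusted p = 0.0857). Unstimulated ST-HSC had 33.5% ± 8.50 and 23.4% ± 15.3 (exact adjusted p = 0.4), stimulated LT-HSC 9.01% ± 5.40 and 22.9% ± 5.85 (0.0635), and stimulated ST-HSC 11.2% ± 8.10 and 1.43% ± 3.19 (0.1048).

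Old minus young had 1 sign in both plate sets: -39.9 and -43.7 percentage points in unstimulated LT-HSC of sets A and B, 24.5 and 15.4 in unstimulated MPP, and 22.3 and 31.2 in stimulated MPP. Set A holds 1 young unstimulated animal. Leaving out any of the 9 mice ended the call in stimulated MPP, where the difference stayed between 24.01 and 26.99 points. The exact p was then the smallest possible, 0.0179 without an old and 0.0286 without a young mouse, so the loss follows from the number of animals and the adjustment. Keeping all cells ended it too, at 14.2 points (adjusted p = 0.0952; 0.0429 to 0.1286 over its alternatives). In the 7 animals with both treatments, the cycling share was lower in stimulated than unstimulated cells by 33.4 points in MPP (45.4% against 78.8%) and by 21.8 in ST-HSC (7.41% against 29.2%), in 7 of 7 animals each (exact p = 0.0156, adjusted p = 0.0234). In LT-HSC it was lower by 13.2 points (14.2% against 27.4%, 5 of 7, exact adjusted p = 0.1094).

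**Figure D4:**
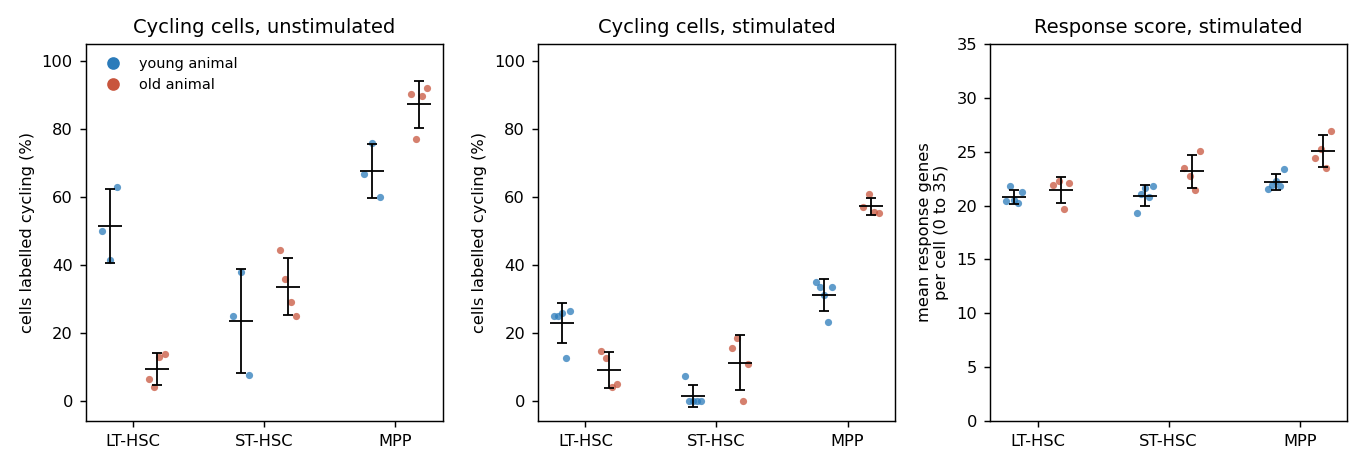
Cells labelled cycling by the submitters (%) without and with stimulation, and mean number of response genes detected per stimulated cell (0 to 35), per animal in LT-HSC, ST-HSC and MPP of young (blue) and old (red) animals; lines with error bars show the mean ± SD over animals. The mean cycling share was lower in old than young LT-HSC and higher in old than young MPP.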

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

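The shares labelled cycling and above the response threshold by age, the tests on genes and lists in the last paragraph and Dixon's criterion were set before the data were examined, and the tests of the cycling share and Rn45s for the response score and of free RNA over the plasma and B cell list before their result was seen. The others were chosen after the data were seen: the mean response score, the difference in the cycling share between LT-HSC and MPP, the plasma-labelled share by age, and the tests of plate set, depth, baseline, genes of every kind, plasma and B cell genes that young cells lack, Igj alone and relabelled samples.

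In unstimulated cells the age difference in the share labelled cycling ran in opposite directions, and its difference between LT-HSC and MPP was -61.86 percentage points (4 old and 3 young animals; exact permutation p = 0.0286, the smallest possible), although neither population passed alone (adjusted p = 0.0635 and 0.0857). Were the plate set the cause, the differences would lose their sign within a set; 4 of 4 kept it. Were the depth of the cells the cause, equal depth would remove it; old LT-HSC then detected 6.11 cell cycle genes per cell against 12.7 in young ones, a difference of -6.57 (exact adjusted p = 0.0429). Both values argue against these causes as the whole of it, and age, the difference the design names, stays open as a hypothesis that was not tested further. How the submitters set the cycling label is not given in the labels and was not tested.

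More response genes were detected per stimulated cell in old than young MPP (25.02 ± 1.48 against 22.2 ± 0.713; SD, n = 4 and 5; exact adjusted p = 0.0238) and ST-HSC (23.2 ± 1.52 against 20.9 ± 1.02; exact adjusted p = 0.0476), while the planned share of cells above the threshold, near its ceiling in both ages, did not pass. A rise in genes of every kind is a candidate explanation: at equal depth old MPP detected 4376.6 genes per cell against 3602.7 (exact adjusted p = 0.119) and old ST-HSC 3510.8 against 3016.4 (0.2262). Of 1000 random sets of other genes matched on detection, 33.6% differed by as much as the score in MPP (median 2.661, score 2.83) and 8.0% in ST-HSC (1.715 and 2.244), so nothing specific to response genes was shown. The cycling share and Rn45s are argued against as the whole cause: the difference was 2.71 genes in MPP and 2.02 in ST-HSC not labelled cycling (exact p = 0.0159 and 0.0317), and 2.72 and 2.48 with Rn45s removed before thinning (exact p = 0.0079 each). A higher baseline stays open, with 1.25 more genes in unstimulated old MPP (n = 4 and 3; exact p = 0.1143) and a gain of 15.8 against 13.97 with stimulation (exact p = 0.0857), as does age.

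Outside the cells compared, 53 single-cell wells carry the submitters' plasma label, all in the MPP sort and 0 of them among 1364 LT-HSC and ST-HSC wells; 29 come from old mouse 3, 22 of them from its unstimulated MPP. They made up 13.7% ± 9.004 of MPP wells of old (SD, n = 4) and 0.968% ± 1.44 of young animals (n = 5; exact p = 0.0159, 0.0357 without old mouse 3 and 0.0571 without young mouse 1, 2, 2-3 or 3), higher in old in 2 of 2 plate sets, which argues against the plate set as the whole cause (11.29% and 17.74% against 3.23% and 1.61% in B; 23.39% in mouse 3 and 2.42% in mouse 2 against 0.0% in A). Free RNA from plasma cells in every well is argued against by bounds chosen after the values were seen: the 7 genes of the plasma and B cell list under 1 CPM in kept young LT-HSC and ST-HSC, such as Igj, the joining chain, Mzb1 and Derl3, came to 1.07 CPM in kept old ones, 0.00296% of their 36170 CPM in labelled wells, and Igj alone to 0.000613% of its 32780 CPM. The list as a whole, at 1.006% of its share in labelled wells against a bound of 1% written before, decides nothing, since 99.76% of its counts in those old cells came from the other 7 of its 14 genes, such as Xbp1 (231.8 CPM) and Irf4 (122.6 CPM), which kept young ones hold as well. Plasma cells caught in the MPP sort, whose gates the labels do not give, are a candidate source with Mzb1 (1087 CPM), Sdc1 (905.5 CPM) and Creld2 (1947 CPM) also high; age stays open.

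A sample stood apart from the others of its group in 23 groups, 15.65% of those tested, by Dixon's criterion, which chance meets in about 1 of 20 groups; CPM are without TMM scaling here. Old mouse 2 had 92.86% of stimulated MPP and old mouse 2-2 95.83% of stimulated ST-HSC above the response threshold, against 100% in the other 3 old mice. Old mouse 2-3 had a mean score of 19.65 in stimulated LT-HSC (others 21.91 to 22.25) and the highest share of Rn45s there, 25.87% (others 13.56% to 15.64%). The cycling share was 12.5% in stimulated LT-HSC of young mouse 2-3, 76.92% in unstimulated MPP of old mouse 2-2 and 7.14% in stimulated ST-HSC of young mouse 1. Nfkbia was at 1641 CPM in stimulated MPP of old mouse 2 (others 1932 to 1990), Il1b at 106.4 CPM in stimulated LT-HSC of old mouse 3 and Vwf at 7.622 CPM in its stimulated ST-HSC.

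The rest were genes at 0.3053 CPM or less in every other animal of the group. Klf5 was at 0.1121 CPM in unstimulated LT-HSC of old mouse 2-3, 1.274 and 0.04905 CPM in unstimulated MPP and ST-HSC of old mouse 2, 2.404 CPM in stimulated MPP of young mouse 3 and 5.82 CPM in stimulated ST-HSC of young mouse 2-3. Tnf was at 0.8078 and 5.761 CPM in unstimulated LT-HSC and ST-HSC of old mouse 2-2, and Il6 at 0.9739 and 0.04905 CPM in unstimulated MPP and ST-HSC of old mouse 2. Slamf1 was at 0.4754 CPM in stimulated MPP of old mouse 2, 2.279 CPM in unstimulated MPP of old mouse 3, 2.394 CPM in stimulated MPP of young mouse 2-1 and 2.32 CPM in stimulated ST-HSC of young mouse 3.

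Effects that differed between groups by a test of the difference itself were the stimulation response of MPP against LT-HSC (0.782% of 14451 genes) and that of ST-HSC against LT-HSC (0.0277%, which is 4 genes), where chance cannot be excluded since 2 of 25 labellings gave as many. The age difference in the response of LT-HSC passed for Coq10b alone (0.00771% of 12970 genes); chance cannot be excluded there either (4 of 24 labellings), and 0 genes passed with the animal as a block. The HSC ageing list passed in the age difference of the response of ST-HSC as a rank against other genes (adjusted p = 0.00112), with 0 of 26 members past the test.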

How the results depend on the processing

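All alternatives were planned except those without Rn45s, without the stimulated sums of young mouse 1, with Rn45s out before thinning and with all reads, which were chosen after seeing the data; the cause of each change was not tested unless given. Of 7935 values of named genes, 7338 kept direction and side of the threshold and 12 reversed, while the others lost or gained a call. Depth limits genes within a few counts of 0, whose counting intervals are wide. Simulated log2 changes of 1, which do not test this limit, were found in 4.5%, 12.1% and 20.9% for the responses of LT-HSC, ST-HSC and MPP.

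Numbers of genes are given as percentages of the genes tested in the comparison as reported, whatever number an alternative tested, so that they are proportional to the counts. The stimulation responses of LT-HSC, ST-HSC and MPP (18.4%, 18.2% and 21%) stayed within 1.5 times in all settings except pools (3.35%, 2.17% and 0.987%), where 2338, 2947 and 1216 genes could be tested, and MPP without cycling cells (3.55%). DESeq2 gave 3.21%, 1.54% and 1.17% for age in stimulated LT-HSC, ST-HSC and MPP and 1.66%, 0.707% and 0.600% in unstimulated ones. It gave 1.4%, 0.856% and 0.695% for the interaction, 3.24% for the response of MPP against LT-HSC and 3.45% for ST-HSC against LT-HSC. Without the filter on low counts these were 2.04%, 0.738% and 0.821%, then 1.09%, 0.471% and 0.545%, then 0.409%, 0.44% and 0.45%, then 2.77% and 5.12%, and 15.8% for MPP against LT-HSC.

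Without cycling cells the old unstimulated MPP arm is 1 sum of 6 cells, mouse 2-2, assumed to vary like the other groups. Each value of this setting that uses it (the response of MPP, age in unstimulated MPP, its interaction, MPP against LT-HSC and the response difference) mixes the loss of cycling cells with that of 3 animals. The values were 0.146%, 0.0157% and 0% for age in stimulated LT-HSC, ST-HSC and MPP and 0.0231% and 0.284% in unstimulated LT-HSC and MPP. They were 0.134% for the interaction in MPP, 2.08% for MPP against LT-HSC and 0.465% for ST-HSC against LT-HSC. Log2(mean TPM + 1) and + 0.1 gave 0.779% and 0.578% for age in stimulated LT-HSC, 0.102% and 0.0942% in ST-HSC and 0.079% and 0.0711% in MPP. In unstimulated cells they gave 0.355% and 0.177% in LT-HSC and 0.00785% with each in ST-HSC. With + 0.1 the value was 0.0079% in unstimulated MPP and 0 for the interaction in LT-HSC, and with + 1 it was 1.29% for the response difference and 2.7% for ST-HSC against LT-HSC. Pools gave 0.0694%, 0% and 0% for age in stimulated LT-HSC, ST-HSC and MPP, 0.0308% in unstimulated LT-HSC and 0 and 0.0079% for the interaction in LT-HSC and MPP. They gave 0.00692% for the response difference, 0.623% for MPP against LT-HSC and 0.0332% for ST-HSC against LT-HSC. The animal as a block gave 0 for the interaction in LT-HSC and 0.381% for the response difference. No plate set term gave 0.0308% for age in unstimulated LT-HSC. All single cells gave 0.0079% in unstimulated MPP and 0.0231% for the interaction in LT-HSC. Leaving out the stimulated sums of young mouse 1 gave 0.509% in stimulated LT-HSC and 0.0079% in unstimulated MPP.

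Leaving out each animal in turn gave 13.2% to 18.6%, 12.9% to 18.5% and 14.9% to 21.5% for the responses of LT-HSC, ST-HSC and MPP. It gave 0.0231% to 0.0771%, 0% to 0.00785% and 0% to 0.0237% for age in unstimulated and 0.162% to 0.424%, 0% to 0.055% and 0% to 0.0553% in stimulated cells, and 0% to 0.0231%, 0% to 0.00785% and 0% to 0.0079% for the interaction. It gave 0.339% to 0.72% for the response difference, 6.79% to 11.4% for MPP against LT-HSC and 0.689% to 1.46% for ST-HSC against LT-HSC. The age difference in the cycling share was -47.2 to -36.4, 2.08 to 17.3 and 15.9 to 23.9 points in unstimulated LT-HSC, ST-HSC and MPP, and -16.5 to -12.2, 7.30 to 13.5 and 24.01 to 26.99 in stimulated ones. That in the share above the response threshold was 3.19 to 4.30, 2.32 to 5.89 and 0.967 to 4.20. That share passed in LT-HSC with Rn45s out (6.98 points, adjusted p = 0.0476; 0.0476 to 0.4048 over its alternatives). The cycling share of stimulated MPP did not pass with all single cells (14.2 points, adjusted p = 0.0952; 0.0429 to 0.1286 over its alternatives), and the number of cell cycle genes detected differed in unstimulated LT-HSC, ST-HSC and MPP by -6.57, 3.04 and 6.36 genes (exact adjusted p = 0.0429 each, the lowest over their alternatives, which reached 0.1286, 0.8667 and 0.7143).

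Directions reversed in pools for Fam212a (0.49) and Inpp5d (0.048) with age in stimulated LT-HSC, Nfkb2 (-0.34) with age in unstimulated MPP, Mpo (-3.58) in ST-HSC against LT-HSC, and Clec4e (-2.21), Errfi1 (0.77), Pdgfb (-2.70), Ptger2 (1.76) and Spp1 (2.17) in the response difference, without cycling cells for Kpna2 (0.46) with age in unstimulated LT-HSC and Coq10b (0.08) in the response difference, and with log2(mean TPM + 1) for Ptger2 (0.12) there. With an estimated correlation 47 list values lost a call and the others kept their side, so that lists past the threshold numbered 2, 0 and 1 for age in stimulated LT-HSC, ST-HSC and MPP, 5, 1 and 0 in unstimulated cells, 0, 1 and 0 for the interaction, 0 for the response difference, 5 for MPP against LT-HSC and 4 for ST-HSC against LT-HSC. With the animal as a block they were 2 and 1 for the interaction in LT-HSC and MPP and 0 for the response difference. Without cycling cells they were 0 in stimulated ST-HSC and MPP, 3 and 1 in unstimulated ST-HSC and MPP, 2 and 0 for the interaction in LT-HSC and MPP and 0 for the response difference, and lists turned direction, with an adjusted p that was the highest over their alternatives except for interferon response (0.739 with an estimated correlation): cell cycle with age in stimulated ST-HSC (adjusted p = 0.891), unstimulated ST-HSC (0.758) and the interactions of LT-HSC (0.988) and MPP (0.889), erythroid with age in unstimulated LT-HSC (0.303) and ST-HSC (0.647), interferon response in unstimulated LT-HSC (0.019), and heat shock, HSC ageing and STAT3 and SOCS genes in unstimulated MPP (0.986 each, with 1 old animal).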

Other observations

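The comparison of MPP with ST-HSC, the detection shares, the scores between populations and all relabelled splits in this part were chosen after the data were seen; the tests on Itgb3, on Tnf with Il6 and on Nupr1 with Selp were written before.

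MPP and ST-HSC were also compared without stimulation. Mpo was at 1548 ± 1120 CPM in MPP and 34.03 ± 23.8 CPM in ST-HSC (SD, n = 7 each; log2 fold change 5.53 ± 0.45, adjusted p = 3.51e-07), Dntt at 705.2 ± 250 against 21.6 ± 22.2 CPM (5.82 ± 0.79, 0.000688), and Ctsg, the granule protease cathepsin G, at a ratio of 13900 (95% counting interval 2500 to 551000). Procr was at 12.6 ± 4.35 against 119.2 ± 24.8 CPM (-3.21 ± 0.32, 5.66e-06) and Tgm2 at 3.27 against 130.8 ± 36.3 CPM (-5.22 ± 0.55, 9.14e-06). In all 1.74% of 12041 genes were higher and 2.27% lower in MPP, or 4.003% together. For unstimulated MPP against ST-HSC this was 8.305% with DESeq2, 9.326% without the filter on low counts, 6.727% with log2(mean TPM + 1), 0.2658% in pools and 0.3405% without cells labelled cycling, where 1 of 4 old MPP sums was left. It was 2.35%, 2.06% and 1.752% without old mouse 2, 2-3 or 3 and 2.475% without young mouse 2-1. Of HSC identity genes 13 of 25 were lower (2.48e-29), of HSC ageing genes 11 of 29 (1.59e-10), of megakaryocyte genes 3 of 20 (1.88e-05) and of interferon response genes 4 of 29 (2.94e-07), and myeloid genes (3 of 19, 9.38e-11) and lymphoid genes (2 of 10, 9.84e-08) were higher, all also with an estimated correlation, as for NF-κB genes (1 of 28 lower, 0.0233). Cell cycle genes (8 of 36 higher, 3.19e-27; adjusted p = 0.0543 with an estimated correlation), oxidative phosphorylation genes (3 of 71 higher, 1.52e-09; adjusted p = 0.25) and STAT3 and SOCS genes (2 of 13 lower, 0.0349; adjusted p = 0.25) did not hold.

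In single stimulated cells read at equal depth, Ccl5 was detected in 63.1% ± 5.65 of MPP and 23.7% ± 13.7 of LT-HSC (SD, n = 9). Cd83 was in 83.9% ± 7.23 and 49.3% ± 18.2, and the NF-κB inhibitor Tnfaip3 in 85.1% ± 12.4 and 62.1% ± 10.1. Each gene had an exact permutation adjusted p = 0.0169, over 26 tests. Ptgs2 went the other way, in 23.3% ± 9.83 of MPP and 47.7% ± 25.3 of LT-HSC, higher in MPP in 1 of 9 animals (exact adjusted p = 0.0254). ST-HSC exceeded LT-HSC for Ccl5 (44.6%, exact adjusted p = 0.0254) and Cd83 (88.3%, 0.0169) and lay under them for Itgb3 (83.5%, 0.0451), while Tnf (19.9%, 0.1016), Ptgs2 (32.1%, 0.2031) and Tnfaip3 (70.7%, 0.3385) did not pass. Unstimulated LT-HSC, ST-HSC and MPP detected Cd83 in 0.9%, 2.0% and 1.4% of cells and Ccl5 in 0.4%, 1.1% and 2.7%. Neither Il6 (12.8% of MPP, 16.5% of LT-HSC) nor the receptors Tlr2 (31.5% and 29.8%) and Tlr4 (4.24% and 6.62%) passed. The mean response score of stimulated MPP was 2.34 genes above LT-HSC and 1.53 above ST-HSC, in 9 of 9 animals each (exact adjusted p = 0.0117). Means were 23.5 in MPP, 21.9 in ST-HSC and 21.1 in LT-HSC, and 8.64, 7.78 and 8.29 without stimulation. MPP also detected more genes of every kind and no matched sets were drawn, so nothing specific to response genes was shown.

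3 hypotheses on single cells were tested within animals. LT-HSC with more Itgb3 reads may have higher response scores: the mean within-animal Spearman's rho was 0.134 over 9 animals, above 0 in 6 of them (exact permutation p = 0.1328). MPP that detect Tnf may detect Il6 more often: 17.5% of MPP with Tnf and 5.40% without it did, a mean difference of 12.15 percentage points, above 0 in 6 of 9 animals (exact p = 0.0859). For both, a p of 0.05 or more had been set before as the outcome against the hypothesis, but a spread between animals (SD 0.2364 and 22.28) above the mean excludes neither a link nor its absence, so both stay open. Unstimulated old LT-HSC with Nupr1 were tested for more frequent Selp: 77.4% with and 79.2% without Nupr1 detected it, a difference of -1.77 points (SD 14.05), above 0 in 2 of 4 animals (exact p = 0.875). A mean of 0 or less, or of either sign between animals, had been set before as the outcome against it, but a mean within its spread over 4 animals, whose exact p cannot fall under 0.125, leaves this link open too.

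Numbers of genes were set against other labellings of the same samples; the share of labellings with as many genes was 1 of 25 unless given otherwise. For the stimulation response no other labelling of treatments within an age reached the real 18.4% of tested genes in LT-HSC (highest other 1.06%), 18.2% in ST-HSC (1.30%) or 21% in MPP (1.81%). Nor did labels swapped within animals (0.0154%, 0% and 2.93%). Chance can be excluded for the age difference in unstimulated LT-HSC (8 genes, 1 of 35, highest other 3), stimulated LT-HSC (41, highest other 2) and stimulated MPP (5, highest other 2), for ST-HSC against LT-HSC (1.46% of tested genes, highest other 0.125%), MPP against LT-HSC (10.35%, 0.382%) and, for the count as reported, the difference of their responses (0.782%, 0.498%, or 72 genes). In stimulated MPP the age difference rests on 5 genes, and 0 passed with edgeR without any 1 of the 4 old mice, without cells labelled cycling or in pools. In unstimulated LT-HSC 3 genes, as many as the highest other, passed without old mouse 2-3 or without cells labelled cycling. For the difference of the responses of MPP and LT-HSC 55 genes passed with the animal as a block, and 49 to 72 without old mouse 2, 2-2 or 2-3 or young mouse 2-1 or 2-3, all within the range of the relabelled counts of all animals. Chance cannot be excluded for the age difference in unstimulated MPP (2, 4 of 35, highest other 5) and stimulated ST-HSC (5, 2 of 25, highest other 5), or for the difference in response of ST-HSC against LT-HSC (4, 2 of 25, highest other 5). Nor can it be for the interaction in LT-HSC (1 gene, 4 of 24, highest other 1). Where the real count is 0, every labelling reaches it and nothing is learnt about chance. This holds for the age difference in unstimulated ST-HSC (90 genes by DESeq2, 35 of 35, highest other 2). It also holds for the interaction in ST-HSC (0.856% by DESeq2, 24 of 24, highest other 1) and MPP (88 genes by DESeq2, 24 of 24, highest other 4). For each interaction 1 drawn labelling could not be fitted.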
